A study of Homo sapiens with 6 samples.

How the data were processed

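Total RNA from DMS-53 cells, a human small cell lung cancer line, was hybridized to 6 Affymetrix U133 Plus 2.0 arrays, 2 each for cells in control medium, in medium with the iron chelator desferrioxamine (DFO, 250 µM) and in medium with the thiosemicarbazone chelator Dp44mT (25 µM). Exposure was for 24 h, and RNA was extracted with TRIzol and labelled with biotin, per the labels' protocols. The arrays of each group are numbered 1 and 2 after the set numbers of the sample titles. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

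The deposited values are probe set intensities on a linear scale, made with Affymetrix Expression Console 1.1 per the submitters' processing notes, which name no summarization or normalization. Values of 54675 probe sets were read for each array, and no other per-sample values were used. The deposited intensities were checked for a common scale and did not have one: the array medians ran from 49.9 to 88.9. The plan fixed before the data were examined took log2(intensity + 16) without further scaling for linear values and listed quantile normalization as an alternative. Because the arrays differed in brightness, the log2(intensity + 16) values were quantile normalized across the 6 arrays with limma 3.58.1 in R 4.3.3, and the unscaled values became the alternative. That change was made after the array medians were seen. On the unscaled values, 26 genes passed for DFO (18 higher, 8 lower) and 56 for Dp44mT (23 higher, 33 lower).

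Probe sets were matched to gene symbols with the platform's annotation. A single symbol was given for 41097 probe sets, several symbols for 1801 and none for 11777. Probe sets with a single symbol were kept, and each gene was represented by its probe set with the highest mean over the 6 arrays. Genes with a mean below the 25th percentile of all probe sets, 5.55 on the log2 scale, were left out, which left 16868 genes. Genes whose probe sets carry several symbols, such as FTH1 and CA9, were not analysed here.

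Group means were compared with limma's moderated test, two-sided, with all 3 groups in the model (3 residual and 2.23 prior degrees of freedom). The contrasts were DFO against control, Dp44mT against control and Dp44mT against DFO. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Fold changes are given as log2 differences of group means, with the standard error of the moderated test and, where given, its 95% interval. The number of arrays, 2 per group, limits the precision: the median half-width of the 95% intervals was 0.64 on the log2 scale. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333 and was not used.

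Sets of genes were tested with limma's camera with a preset correlation of 0.01, adjusted over 25 lists within a contrast, again with the correlation estimated from the data, and with fry. The lists were iron uptake, storage and export, haem and iron-sulfur cluster synthesis, HIF targets outside glycolysis, glycolysis, JmjC demethylases, immediate early genes, NF-kB and cytokine genes, p53 targets, the GADD family, ATF4 and amino acid response, the unfolded protein response, heat shock proteins, NRF2 targets, metallothioneins and zinc export, autophagy and lysosome, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis, the respiratory chain, sterol synthesis, neuroendocrine markers, common reference genes, and markers of fibroblasts, endothelium and leukocytes. Some genes stand in more than 1 list, for example DDIT3 and PPP1R15A (ATF4 and GADD lists), KDM3A and KDM4B (HIF and demethylase lists), SESN2 (ATF4 and p53 lists) and ENO2 (glycolysis and neuroendocrine lists). Members past the threshold were counted over all genes tested and also adjusted over the list alone.

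The groups, contrasts, thresholds, lists and the rule for naming genes were set before the data were examined. The rule named a fixed set of anchor genes (TFRC, FTH1, NDRG1, VEGFA, EGLN3, CDKN1A, GADD45A, DDIT3, CCND1, RRM2, HMOX1 and MT2A), the 10 largest increases and 10 largest decreases of each chelator among the genes past the threshold whose treated arrays both lay on the same side of both control arrays, and up to 4 members of each list, those past the threshold by size of change or else those with the smallest p. Genes outside it are marked in the text as chosen after their values were seen.

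Because both chelators are compared with the same 2 control arrays, the overlap and correlation of their fold changes were set beside 50 simulations in which the treated groups were unchanged but shared the controls. The calls were also tested on simulated data with known changes in 20 draws per contrast. A true change of 2 on the log2 scale was recovered for 71.5% of changed genes in DFO and 70.3% in Dp44mT, a change of 1 for 3.62% and 3.02%, and 5.87% and 5.58% of the calls were false. For the glycolysis list, a shift of 1 was called in 20 of 20 draws. These draws used independent noise with 1 spread per gene, equal in all groups. On the real arrays, the SD of the difference between replicates was 0.404 in control, 0.677 in DFO and 0.771 in Dp44mT. The deviations of same-numbered DFO and Dp44mT arrays also correlated at 0.843, so the simulated rates need not hold for these data.

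The alternatives tried were the unscaled values, subtraction of the array medians, no filter and a filter at the 50th percentile, the mean of a gene's probe sets, every probe set by itself, trended and robust variance moderation, the set number as a block, a model of only the groups compared, pseudocounts of 1 and 64, stricter thresholds and leaving out each array. Linear scaling to a common median, array weights, leaving out both chelator arrays of set 2 and a crossed pairing were added after the data were seen. Probe sets were placed next to their genomic neighbours with a gene table for the closing observations alone.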

Results

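Gene expression was measured in DMS-53 small cell lung cancer cells kept for 24 h in control medium, in 250 µM DFO or in 25 µM Dp44mT, with 2 arrays per group. DFO is an iron-binding siderophore, and Dp44mT is a membrane-permeable thiosemicarbazone that binds iron and copper. The series' design text gives the aim of the conditions as a rise of iron-responsive genes such as the transferrin receptor, and the higher dose of DFO as an answer to its poor entry into cells. The median deposited intensity was 88.9 and 88.8 on the control arrays, 85.5 and 63.0 on the DFO arrays and 83.6 and 49.9 on the Dp44mT arrays. Replicate arrays correlated across genes at 0.971 in control, 0.918 in DFO and 0.892 in Dp44mT after normalization, where genes are not independent replicates. The DFO and Dp44mT arrays of set 2 were the dimmest, and they lay at 48.3 and 84.4 on the first principal component (71.1% of the variance), against −24.8 and 0.319 for the chelator arrays of set 1. The ratio of 3' to 5' signal of the ACTB control probe sets, a measure of RNA integrity, ran from 1.14 to 1.41 over the 6 arrays.

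**Figure D1:**
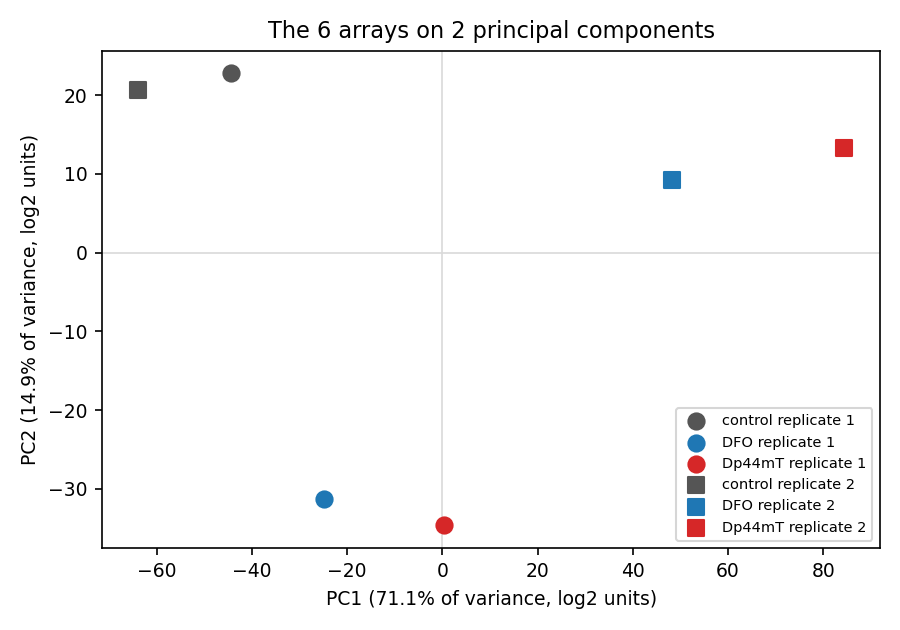
Scores of the 6 arrays on the first and second principal components of the normalized log2 intensities of all genes tested (log2 units), with circles for set 1 and squares for set 2. The control arrays lie at −44.3 and −64.0 on the first component, and the set 2 chelator arrays lie at 48.3 (DFO) and 84.4 (Dp44mT).

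The comparison of DFO with control asked which genes respond to the siderophore. A total of 175 genes were up-regulated and 10 were down-regulated in DFO as compared to control, among 16868 genes tested. Among the largest increases was that of BHLHE40, a hypoxia-inducible repressor of the circadian clock, by 39.0-fold (log2 5.28, SE 0.16, n = 2 arrays per group, adjusted p = 0.00502). TNFAIP3, a ubiquitin-editing inhibitor of NF-kB signalling, and ADM, which encodes the vasodilator adrenomedullin, rose by 28.8-fold and 21.9-fold, respectively (log2 4.85, SE 0.19, and 4.45, SE 0.23). The transcription factor gene ATF3 rose by 21.1-fold and FOS by 20.7-fold. ANKRD37, GADD45B, PLOD2, ANGPTL4 and PPP1R3C followed, with increases between 12.8-fold and 17.4-fold. For 6 of the 41 genes called in DFO among those named by rule (BHLHE40, FOS, ANGPTL4, PLK2, CCN2 and CCL20), the control mean lay below the filter limit of 5.55. The size and order of their fold changes therefore depend on the pseudocount. The deposited control intensities were 16.1 and 17.0 for BHLHE40 and 8.67 and 0.00661 for FOS, against the pseudocount of 16. With a pseudocount of 1, FOS, CCN2, PDK1, CCDC154, COA7, INSM1 and KIF20A did not pass in DFO (7 genes, adjusted p between 0.0518 and 0.192).

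Targets of the hypoxia-inducible factors (HIF), whose degradation depends on iron-containing prolyl hydroxylases, were the list with the most increases. In DFO, 23 of 33 measured members rose, 0 fell and 10 did not pass the test, and 28 rose when adjusted over the list alone. The list median was 2.25 on the log2 scale (camera adjusted p = 1.80e-38, and adjusted p = 0.0414 with an estimated correlation). VEGFA, which encodes a growth factor of blood vessels, rose by 5.63-fold (log2 2.49, SE 0.19), the prolyl hydroxylase gene EGLN3 by 6.73-fold (log2 2.75, SE 0.31) and the metastasis suppressor NDRG1 by 4.31-fold (log2 2.11, SE 0.20). Collagen cross-linking enzyme PLOD2 rose by 14.2-fold. Of 18 glycolysis genes, 6 rose and 0 fell, and 12 rose when adjusted over the list alone (median 0.70, camera adjusted p = 6.49e-13, and adjusted p = 0.0469 with an estimated correlation). HK2, the inducible hexokinase, rose by 4.55-fold, the glucose transporter gene SLC2A1 by 4.02-fold and PDK1, a kinase that restrains pyruvate dehydrogenase, by 3.80-fold. When a gene's probe sets were averaged, the HK2 value turned to −0.11. Among 18 JmjC demethylases, an iron-dependent family that removes methyl groups from histones, KDM3A rose by 8.39-fold and KDM4B by 2.88-fold, and 16 did not pass. The median of that list was 0.66 (camera adjusted p = 1.65e-07, and adjusted p = 0.241 with an estimated correlation), with 8 members up when adjusted over the list alone.

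Stress-response genes formed the next groups. Of 20 immediate early genes, 10 rose and 0 fell in DFO (15 when adjusted over the list alone), with a median of 1.62 (camera adjusted p = 9.95e-19, and adjusted p = 0.0414 with an estimated correlation). They included the phosphatase gene DUSP5 (8.42-fold) and CCN2, which encodes a matrix protein (8.30-fold). Of 6 genes of the GADD family, 3 rose: GADD45B by 15.5-fold, DDIT3 (CHOP) by 8.56-fold and PPP1R15A (GADD34) by 7.04-fold. GADD45A stood at 1.30 on the log2 scale with an adjusted p of 0.0513. The GADD median was 2.06 (5 up when adjusted over the list alone, camera adjusted p = 3.19e-07, and adjusted p = 0.0469 with an estimated correlation). Of 25 genes of the ATF4 and amino acid response, 10 rose and 0 fell (12 over the list alone), among them STC2 by 8.05-fold. The ATF4 list median was 0.57 (camera adjusted p = 5.11e-16, and adjusted p = 0.122 with an estimated correlation).

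The unfolded protein response had 2 increases among 15 members (5 when adjusted over the list alone): HERPUD1, a component of endoplasmic reticulum degradation, by 5.07-fold and the co-chaperone gene DNAJB9 by 4.75-fold (median 0.37, camera adjusted p = 4.51e-07, and adjusted p = 0.0469 with an estimated correlation). Of 23 p53 targets, 5 rose (7 when adjusted over the list alone), led by GDF15 at 6.45-fold, SESN2 at 5.34-fold, PLK2 at 4.51-fold and the death receptor gene TNFRSF10B at 3.64-fold. The p53 list median was 0.42 (camera adjusted p = 9.22e-08, and adjusted p = 0.0469 with an estimated correlation), while CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 value of 1.68 (SE 0.38) and did not pass (adjusted p = 0.167). Of 13 NF-kB and cytokine genes, TNFAIP3 and the chemokine gene CCL20 (12.6-fold) rose, and 7 rose when adjusted over the list alone (median 1.00, camera adjusted p = 9.22e-08, and adjusted p = 0.0469 with an estimated correlation). None of 16 autophagy and lysosome genes or 18 NRF2 targets passed by itself in limma (0 and 0), and 3 of each rose when adjusted over the list alone. MAP1LC3B had the smallest p of the autophagy list (log2 1.41, adjusted p = 0.0532), and TXNRD1 that of the NRF2 list (log2 1.04, adjusted p = 0.0947). The medians of these lists were 0.22 and 0.17 (0.30 and 0.24 in set 1, 0.13 and 0.12 in set 2), with camera adjusted p of 0.000895 and 0.00797, and adjusted p = 0.268 and 0.56 with an estimated correlation. The calls ended on the deposited scale, where the medians were −0.13 and −0.15 (adjusted p = 0.0881 and 0.0826), and without DFO replicate 1 (adjusted p = 0.0515 and 0.0766). The NRF2 call also ended with the array medians subtracted (median 0.08, adjusted p = 0.05).

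Genes of mitosis had the lowest median of the lists in DFO. CCNB1, which encodes cyclin B1, fell by 4.17-fold (log2 −2.06, SE 0.18) and the kinesin gene KIF20A by 3.35-fold, and the other 24 of 26 G2/M and mitosis genes did not pass. When adjusted over the list alone, 22 of the 26 were lower. Their median was −1.23 (camera adjusted p = 5.96e-18, and adjusted p = 0.167 with an estimated correlation). In the ribosome biogenesis list, RRS1 fell by 3.93-fold and 15 of 16 did not pass (median −0.37, at −0.16 in set 1 and −0.50 in set 2, camera adjusted p = 0.00481, and adjusted p = 0.55 with an estimated correlation). INSM1, a neuroendocrine transcription factor, fell by 4.61-fold, whereas ENO2, a neuroendocrine marker that is also a glycolytic enzyme gene, rose by 3.35-fold. The 17 neuroendocrine markers had a median of −0.23 and were not called (adjusted p = 0.0767). The largest decreases among the genes called were those of CCDC154 (11.6-fold), OR51E2 (8.66-fold), COA7 (7.83-fold) and FAM83D (4.87-fold). INSM1 and CCNB1 came next, then NPTX1 (4.08-fold), RRS1 and MYCL (3.39-fold). Of the 185 genes called, 120 had another probe set, and for 116 of them its median lay on the same side, but the other probe sets of ANKRD37 (1.22), GDF15 (0.31), PPP1R3C (0.19) and MYCL (−0.25) gave far smaller log2 changes.

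Other lists were not called in DFO. The medians were −0.13 for 29 G1/S and DNA replication genes (adjusted p = 0.408), 0.42 for 10 metallothionein and zinc export genes (0.157, at 1.16 in set 1 and −0.20 in set 2), −0.25 for 17 genes of haem and iron-sulfur cluster synthesis (0.274), −0.12 for 13 heat shock proteins (0.789) and −0.23 for 16 genes of sterol synthesis (0.17). The 21 respiratory chain genes had a median of 0.02, a mean of −0.00 and an upward test direction (adjusted p = 0.72). Common reference genes had a median of 0.09 (adjusted p = 0.441). Markers of other cell types had medians of 1.29 for fibroblasts (0.188), 0.61 for endothelium (0.0668, at −0.05 in set 1 and 0.96 in set 2) and −0.15 for leukocytes (0.563). For fibroblasts the median was −0.29 in set 1 and 3.12 in set 2, a difference that stands beside every list above, since the set 2 arrays enter each of them.

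With control replicate 1, control replicate 2, DFO replicate 1 or DFO replicate 2 left out, 0 genes passed in limma (1065, 889, 2432 and 1341 at an unadjusted p under 0.05), 61 passed without either Dp44mT array, and 0 passed (3185 unadjusted) without both set 2 chelator arrays, while all 185 genes kept their sign in each. Those signs could not change when arrays were left out, because in all 185 genes both DFO arrays lay on 1 side of both control arrays. On the deposited scale, where the median of all genes was −0.32, 26 genes passed (18 higher, 8 lower, against 94.6% higher among the 185), with 97 when the array medians were subtracted (85 higher, 12 lower).

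The comparison of Dp44mT with control asked the same of the thiosemicarbazone. Relative to control, 323 genes were up-regulated and 246 were down-regulated in Dp44mT. Among the largest increases were those of BHLHE40, by 42.0-fold (log2 5.39, SE 0.16, n = 2 arrays per group, adjusted p = 0.00452), TNFAIP3 at 35.3-fold, FOS at 26.8-fold, ATF3 at 24.6-fold and ADM at 21.1-fold. NEURL3, which encodes a ubiquitin ligase, rose by 18.6-fold and CSRNP1 by 13.1-fold. CCDC154 fell by 47.5-fold and OR51E2 by 15.1-fold. For 9 of the 66 genes called in Dp44mT among those named by rule, the mean of the lower group lay below the filter limit of 5.55: 7 increases (BHLHE40, FOS, NEURL3, ANGPTL4, PLK2, OSGIN1 and CCL20) and 2 decreases (CCDC154 and OR51E2). The size and order of these fold changes therefore depend on the pseudocount. The deposited intensities of CCDC154 in Dp44mT were 13.9 and 0.0403, below the pseudocount of 16. With a pseudocount of 1, 9 of the genes named by rule lost the threshold in Dp44mT (BAG3, DLGAP5, DNAJC3, HSPE1, JMJD6, KDM2A, KIF11, SQSTM1 and TOP2A, adjusted p between 0.0511 and 0.061). TGFB2, which encodes a transforming growth factor, fell by 13.7-fold, LMO3 by 13.2-fold, NPTX1 by 12.1-fold, the neuroendocrine factor INSM1 by 10.3-fold and the arginine methyltransferase gene PRMT6 by 8.80-fold. Other probe sets of called genes lay on the same side for 317 of 343 genes, with −0.92 for LMO3.

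HIF targets again had 23 of 33 members up and 0 down (27 when adjusted over the list alone), with a median of 2.20. The camera adjusted p was 7.15e-23, and adjusted p = 0.0824 with an estimated correlation. VEGFA rose by 5.01-fold (log2 2.33, SE 0.19), EGLN3 by 5.48-fold and NDRG1 by 4.05-fold. Glycolysis had 6 of 18 members up, among them HK2 (4.71-fold), ENO2 (4.09-fold), ALDOC (3.79-fold) and PDK1 (3.23-fold), and 13 up with 1 down when adjusted over the list alone. Its median was 0.64 (camera adjusted p = 1.02e-07, and adjusted p = 0.0824 with an estimated correlation), and the averaged probe sets of HK2 gave −0.38. JmjC demethylases had 4 of 18 members up: KDM3A (9.49-fold), KDM4B (3.18-fold), JMJD6 (2.34-fold) and KDM2A (2.14-fold). That list had a median of 0.59 and 10 up with 1 down when adjusted over the list alone (camera adjusted p = 4.28e-05, and adjusted p = 0.334 with an estimated correlation), and its median was −0.02 on the deposited scale.

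Among the stress responses to Dp44mT, 12 of 25 ATF4 and amino acid genes rose (20 when adjusted over the list alone), including PPP1R15A by 12.9-fold, DDIT3 by 11.8-fold and STC2 by 9.62-fold (median 1.03, camera adjusted p = 4.56e-15, and adjusted p = 0.129 with an estimated correlation). The unfolded protein response had 5 of 15 up (12 when adjusted over the list alone), with DNAJB9 at 6.75-fold, HERPUD1 at 6.68-fold and SEL1L at 3.32-fold (median 0.78, camera adjusted p = 6.46e-08, and adjusted p = 0.0824 with an estimated correlation). Of the GADD family, 4 of 6 rose (5 over the list alone), with GADD45B at 18.9-fold and GADD45A at 2.80-fold (median 2.53, camera adjusted p = 2.70e-05, and adjusted p = 0.0824 with an estimated correlation). Immediate early genes had 10 of 20 up (13 over the list alone), with EGR1 at 11.2-fold and DUSP5 at 11.4-fold (median 1.57, camera adjusted p = 3.35e-12, and adjusted p = 0.0824 with an estimated correlation). Of 23 p53 targets, 6 rose (8 over the list alone), with SESN2 at 7.56-fold and TNFRSF10B at 4.94-fold (median 0.71, camera adjusted p = 5.12e-05, and adjusted p = 0.0824 with an estimated correlation). NF-kB and cytokine genes had 5 of 13 up (7 over the list alone), with the inhibitor gene NFKBIA at 5.89-fold and RELB at a log2 value of 1.58 (median 1.05, camera adjusted p = 5.02e-05, and adjusted p = 0.0888 with an estimated correlation).

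NRF2 targets, the genes of glutathione and thioredoxin metabolism, had 6 of 18 members up (11 when adjusted over the list alone). OSGIN1 rose by 7.34-fold, GCLC, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, by 3.69-fold, the thioredoxin reductase gene TXNRD1 by 3.05-fold and the sulfiredoxin gene SRXN1 by 3.01-fold. Their median was 0.92 (camera adjusted p = 1.19e-07, and adjusted p = 0.256 with an estimated correlation). HMOX1, the haem oxygenase gene, had a log2 value of 1.81 (SE 0.45) and did not pass (adjusted p = 0.097). Of 10 metallothionein and zinc export genes, MT3 rose by 2.81-fold and 9 did not pass, with 6 up when adjusted over the list alone. The metallothionein median was 2.33, at 1.35 in set 1 and 3.28 in set 2 (camera adjusted p = 0.000145, and adjusted p = 0.401 with an estimated correlation), and MT2A stood at 2.10 (SE 0.58, adjusted p = 0.116). Of 16 autophagy and lysosome genes, MAP1LC3B rose by 2.92-fold, GABARAPL1 by 2.53-fold and SQSTM1 by 2.35-fold (4 over the list alone, median 0.22, at 0.37 in set 1 and 0.12 in set 2, camera adjusted p = 0.00285, and adjusted p = 0.334 with an estimated correlation). The autophagy call ended on the deposited scale (median −0.33, adjusted p = 0.214), with the array medians subtracted (0.04, adjusted p = 0.117) and with linear scaling (0.10, adjusted p = 0.0718).

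Mitotic genes were again lower: 12 of 26 G2/M and mitosis genes fell, and 21 when adjusted over the list alone. DLGAP5 fell by 4.82-fold, the kinesin gene KIF11 by 4.42-fold, CCNB1 by 3.73-fold and the topoisomerase gene TOP2A by 3.69-fold. The list median was −1.49 (camera adjusted p = 3.62e-13, and adjusted p = 0.242 with an estimated correlation). None of 29 G1/S and DNA replication genes passed by itself in limma (0 of 29, and 9 lower when adjusted over the list alone), and the list was called lower with a median of −0.53, at −0.30 in set 1 and −0.74 in set 2 (camera adjusted p = 0.000171, and adjusted p = 0.53 with an estimated correlation). The replication factor gene RFC4 stood at −2.07 (adjusted p = 0.0597) and PCNA, the sliding clamp, at −0.87 (adjusted p = 0.0623). Neuroendocrine markers were called lower, with a median of −0.39, at −0.25 in set 1 and −0.48 in set 2 (camera adjusted p = 0.00991, and adjusted p = 0.435 with an estimated correlation). INSM1 and the lung lineage factor gene NKX2-1 (5.09-fold) fell, ENO2 rose, and 14 of 17 did not pass, with 5 lower and 1 higher when adjusted over the list alone. For ribosome biogenesis, RRS1 fell by 5.23-fold and 15 of 16 did not pass (median −0.41, at −0.08 in set 1 and −0.66 in set 2, camera adjusted p = 0.0239, and adjusted p = 0.53 with an estimated correlation), and the call ended without control replicate 2 (−0.28, adjusted p = 0.113), without Dp44mT replicate 2 (−0.17, adjusted p = 0.0884) and without both set 2 chelator arrays (−0.17, adjusted p = 0.0978).

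In Dp44mT, 2 of 17 genes of haem and iron-sulfur cluster synthesis rose, ALAS1 and ISCA1, both by 2.42-fold, but the list was not called (median −0.35, adjusted p = 0.147). BAG3 rose by 2.33-fold and HSPE1 fell by 2.29-fold among 13 heat shock proteins (median −0.08, adjusted p = 0.887). No call was made for the respiratory chain (median −0.03, adjusted p = 0.63), sterol synthesis (0.19, adjusted p = 0.623) or common reference genes (0.07, adjusted p = 0.814). The marker medians were 1.20 for fibroblasts (adjusted p = 0.134, at −0.23 in set 1 and 2.84 in set 2), 0.60 for endothelium (0.228, at −0.14 in set 1 and 0.93 in set 2) and −0.12 for leukocytes (0.777).

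With control replicate 1, control replicate 2, Dp44mT replicate 1 or Dp44mT replicate 2 left out, 0 genes passed in limma (2069, 1800, 5443 and 2366 at an unadjusted p under 0.05), while all 569 genes kept their sign. Those signs could not change when arrays were left out, because in all 569 genes both Dp44mT arrays lay on 1 side of both control arrays. On the deposited scale, where the median of all genes was −0.49, 56 genes passed (23 higher, 33 lower, against 56.8% higher among the 569), with 247 when the array medians were subtracted (104 higher, 143 lower) and 314 with linear scaling (42.4% higher).

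**Figure D2:**
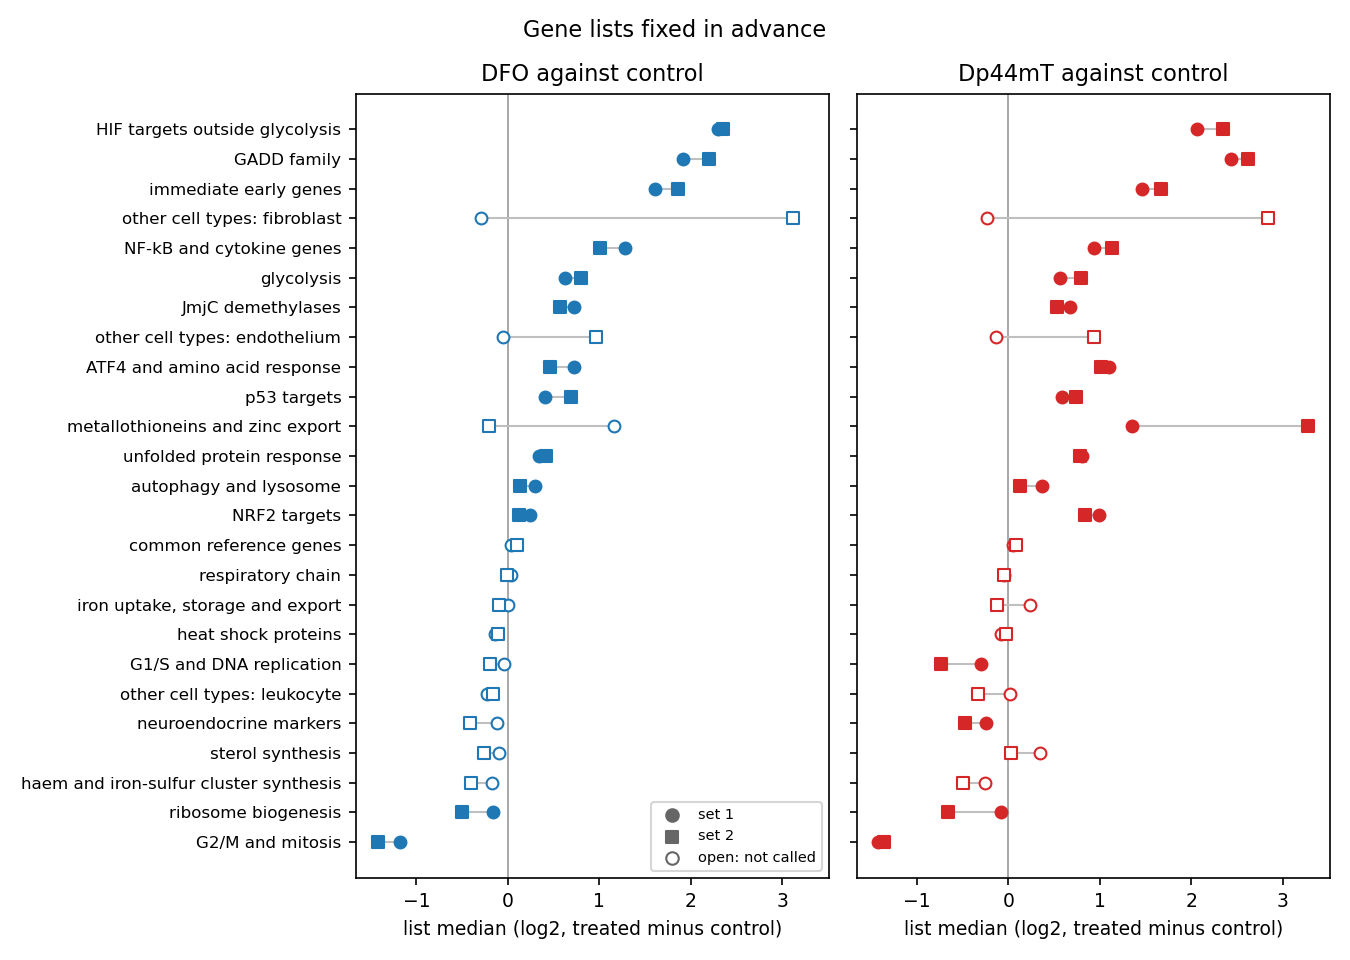
Median log2 change of each fixed gene list against the control array of the same set number, for DFO and Dp44mT, with circles for set 1, squares for set 2 and open symbols where camera's adjusted p was 0.05 or more. In set 1 and set 2, HIF targets lie at 2.30 and 2.35 (DFO) and at 2.07 and 2.34 (Dp44mT). Mitotic genes lie at −1.18 and −1.42 (DFO) and at −1.43 and −1.36 (Dp44mT). Fibroblast markers reach 3.12 (DFO) and 2.84 (Dp44mT) in set 2 alone.

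The transferrin receptor gene TFRC, whose mRNA is stabilized when iron is scarce, was the gene named in the design text. On its brightest probe set it was 1.79-fold higher in DFO (log2 0.84, SE 0.17, 95% interval 0.41 to 1.26) and 1.63-fold higher in Dp44mT (log2 0.70, SE 0.17, 0.27 to 1.13), with n = 2 arrays per group. Neither value passed the threshold over all genes (adjusted p = 0.128 and 0.0909), although both treated arrays lay above both control arrays after normalization. On the deposited scale the log2 values were 0.49 and 0.17, and the intensities of DFO replicate 2 (4350) and Dp44mT replicate 2 (3214) lay below that of control replicate 2 (4694), the latter also below that of control replicate 1 (3330). With trended and robust variance moderation both passed (adjusted p = 0.00581 and 0.0075), and over all settings tried the adjusted p ran from 0.00581 to 0.925 in DFO and from 0.0075 to 0.901 in Dp44mT. When every probe set was tested, 1 of the 4 TFRC probe sets passed, at 2.80-fold in DFO and 2.44-fold in Dp44mT (adjusted p = 0.0433 and 0.0395). Another stood at log2 values of 1.15 and 1.02 and did not pass (adjusted p = 0.0666 and 0.0531), and a dim probe set of TFRC stood at −0.11 and −0.66. The NCOA4 gene, which encodes the receptor for ferritin degradation, stood at 0.60 in DFO and 0.77 in Dp44mT and did not pass. None of the 20 genes of iron uptake, storage and export passed by itself in limma in either chelator (0 and 0 called). The list medians were −0.02 and −0.03, against means of 0.06 and 0.10 and an upward test direction (adjusted p = 0.64 and 0.755). CCND1, which encodes cyclin D1, stood at 1.54 in DFO (adjusted p = 0.143) and 0.68 in Dp44mT (adjusted p = 0.271, and −0.01 on the deposited scale).

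**Figure D3:**
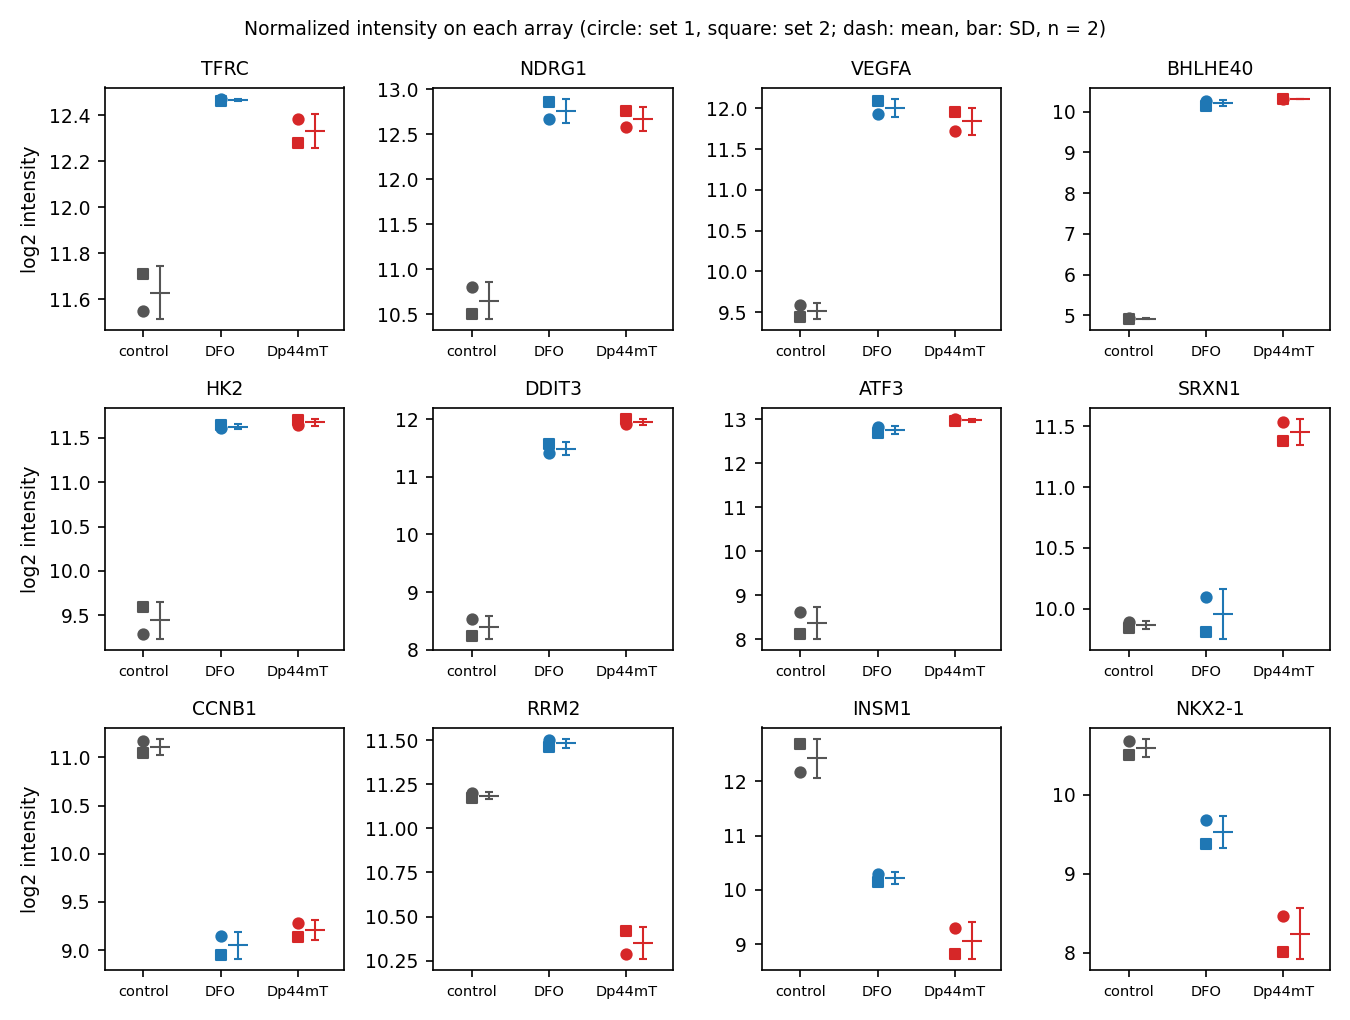
Normalized log2 intensity of 12 genes on each of the 6 arrays (circles set 1, squares set 2), with the mean (dash) and SD (bar) of the 2 arrays of each group, on axes that do not start at 0. TFRC lies 0.84 (DFO) and 0.70 (Dp44mT) above control, and CCNB1 lies at −2.06 and −1.90 from control.

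The chelators were then compared with each other, at doses that differ (250 µM DFO and 25 µM Dp44mT), so the values stand side by side and are not matched by dose. VEGFA stood at 2.49 in DFO and 2.33 in Dp44mT, a difference of −0.17 (95% interval −0.64 to 0.30), and NDRG1 at 2.11 and 2.02, a difference of −0.09 (−0.60 to 0.41). For TFRC the difference was −0.14 (−0.56 to 0.29). RRM2, which encodes the iron-containing subunit of ribonucleotide reductase, stood at 0.30 in DFO (−0.12 on the deposited scale) and −0.84 in Dp44mT, a difference of −1.13 (SE 0.16, −1.54 to −0.72). CCN2 was lower in Dp44mT than in DFO by 4.80-fold (log2 −2.26, −3.23 to −1.29). SRXN1 was higher in Dp44mT by 2.83-fold (SE 0.19 on the log2 scale), OSGIN1 by 3.32-fold (SE 0.25) and SLC30A1, a zinc exporter gene, by 3.32-fold (SE 0.49). No gene passed the test of the difference in limma: 0 of 16868 were called, and the smallest adjusted p was 0.922. An unadjusted limma p under 0.05 was found for 718 genes, a share below the 0.05 that no difference at all would give on average.

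Of the genes called against control, 178 were called with both chelators (168 up and 10 down, 0 in opposite directions), 7 with DFO alone and 391 with Dp44mT alone. Lists called independently would share 3.35 higher and 0.146 lower genes. The fold changes of the chelators correlated across genes at 0.906 (Pearson) and 0.879 (Spearman), with a covariance of 0.424. For unchanged groups that share the controls, simulation gave 0.499, 0.465 and 0.0703, respectively. Genes ranked by p in the same numbers as the calls shared 57.3 of the higher and 5.9 of the lower genes on average in those simulations (44 to 69 and 3 to 9 over 50 draws), against 168 and 10. The simulation covered the shared controls but not the deviation that DFO and Dp44mT arrays of 1 set number have in common (correlation 0.843), so a no-change value with both would lie higher. With the controls split by set number, the changes of single arrays correlated across all genes at 0.307 (DFO set 1 and Dp44mT set 2) and 0.487 (DFO set 2 and Dp44mT set 1), against 0.756 within set 1 and 0.948 within set 2. Changes of the same chelator in set 1 and set 2 correlated at only 0.352 (DFO) and 0.522 (Dp44mT). Over the 576 genes called with either chelator, which were chosen on the same arrays, the values across chelators and sets were 0.958 and 0.962. Those of the same chelator were 0.981 and 0.983. Of the 178 genes, the interval of the difference included 0 for 150 and lay within 1 on the log2 scale in either direction for 139, with a median size of 0.23 and a largest of 2.04. Of the 398 genes called with 1 chelator alone, 166 had an unadjusted p under 0.05 in limma's test of the difference, and 0 passed. The 178 and 398 genes were chosen by their calls on the same arrays. That choice by itself favours small differences among the 178 and large ones among the 398. Without DFO replicate 2 the correlation was 0.632, and with any 1 of the 6 arrays left out 0 genes were shared.

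**Figure D4:**
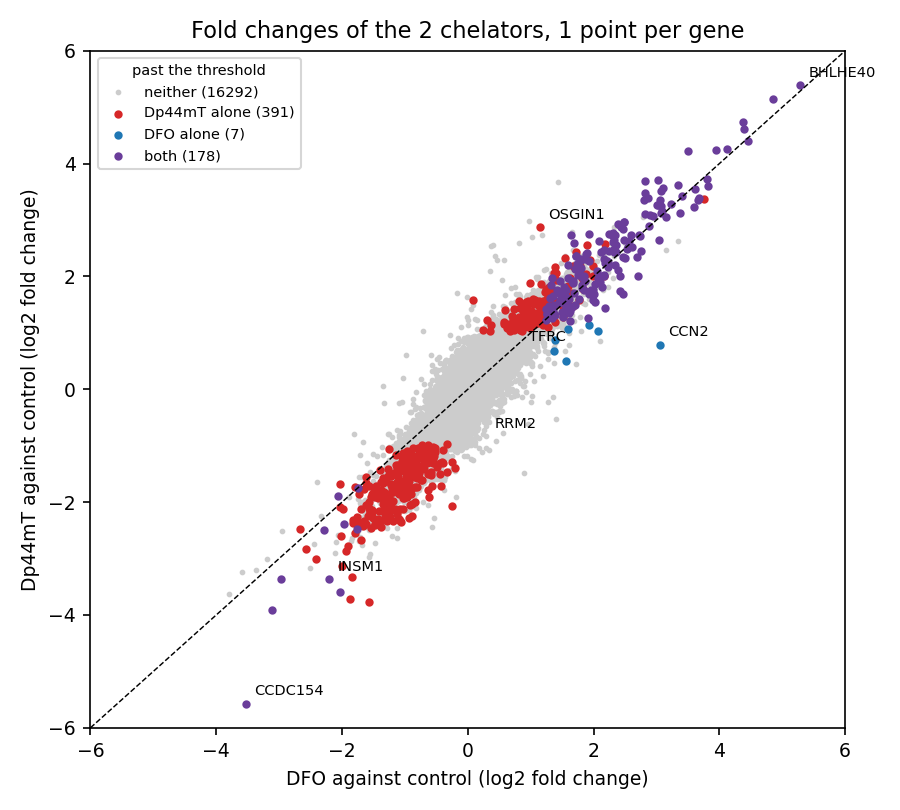
Log2 fold change against control of each gene tested, DFO on the horizontal and Dp44mT on the vertical axis, coloured by the comparisons in which the gene passed (178 both, 7 DFO alone, 391 Dp44mT alone, 16292 neither), with a dashed line of equal change. BHLHE40 lies at 5.28 and 5.39, and CCN2 at 3.05 and 0.79.

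Gene lists differed between the chelators where single genes did not pass. NRF2 targets were higher in Dp44mT than in DFO by a median of 0.67 (camera adjusted p = 3.23e-13, and adjusted p = 0.412 with an estimated correlation), with 17 of 18 members above 0 and 6 higher when adjusted over the list alone. ATF4 and amino acid genes were higher by 0.38 (24 of 25 above 0, camera adjusted p = 2.41e-10, and adjusted p = 0.412 with an estimated correlation), including the pseudokinase gene TRIB3 at 2.14-fold. The unfolded protein response was higher by 0.40 (14 of 15 above 0, camera adjusted p = 1.83e-07, and adjusted p = 0.277 with an estimated correlation). Metallothionein and zinc export genes were higher by 1.81 (10 of 10 above 0, camera adjusted p = 1.65e-06, and adjusted p = 0.553 with an estimated correlation), at 0.22 in set 1 and 3.48 in set 2. Sterol synthesis (0.24, camera adjusted p = 0.00263, and adjusted p = 0.822 with an estimated correlation) and the GADD family (0.27, camera adjusted p = 0.0115, and adjusted p = 0.412 with an estimated correlation) were also higher. G1/S and DNA replication genes were lower by a median log2 of −0.43 (26 of 29 below 0, camera adjusted p = 2.29e-08, and adjusted p = 0.76 with an estimated correlation), with the thymidylate synthase gene TYMS at −0.67. Neuroendocrine markers were lower (−0.16, camera adjusted p = 0.0179, and adjusted p = 0.76 with an estimated correlation), with NKX2-1 at −1.28 and INSM1 at −1.16.

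The other lists were not called between the chelators. HIF targets differed by −0.03 (adjusted p = 0.458), glycolysis by −0.04 (0.837), immediate early genes by 0.22 (0.0952) and p53 targets by 0.02 (0.764). G2/M and mitosis had a median of 0.06, a mean of −0.09 and a downward test direction (adjusted p = 0.684). Median and mean also differed in sign for heat shock proteins (−0.02 and 0.04), JmjC demethylases (0.04 and −0.01), endothelium (0.33 and −0.12) and ribosome biogenesis (−0.01 and 0.01), all with an upward test direction. All 8 calls between the chelators were lost with an estimated correlation, and fry's directional test called 0 of 25 lists and its mixed test 6. The metallothionein call ended without both set 2 chelator arrays (0.22, adjusted p = 0.655), and the sterol and GADD calls ended on the deposited scale (−0.11 and −0.02, adjusted p = 0.272 and 0.163), with the array medians subtracted (0.04 and 0.13, adjusted p = 0.265 and 0.102), with linear scaling (0.07 and 0.16, adjusted p = 0.166 and 0.0529), without Dp44mT replicate 1 (0.01 and 0.38, adjusted p = 0.437 and 0.187) and without DFO replicate 2 (0.06 and 0.40, adjusted p = 0.533 and 0.0727). The neuroendocrine call ended without DFO replicate 1 (−0.03, adjusted p = 0.13), DFO replicate 2 (−0.25, adjusted p = 0.0645) or Dp44mT replicate 2 (0.05, adjusted p = 0.171), and without both set 2 chelator arrays (−0.10, adjusted p = 0.146).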

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

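All explanations weighed here were tested only after the pattern had been seen. The list and gene differences come from contrasts planned beforehand, but picking out genes on opposite sides of control was not in the plan.

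Differences between the chelators were largest by list median for metallothioneins and zinc export, which were higher in Dp44mT than in DFO by 1.81 on the log2 scale. That rank came from set 2: the difference was 0.22 in set 1 and 3.48 in set 2, and without both set 2 chelator arrays it was not called (0.22, adjusted p = 0.655). NRF2 targets (0.67), the unfolded protein response (0.40), the ATF4 and amino acid response (0.38), the GADD family (0.27) and sterol synthesis (0.24) were also higher in Dp44mT. G1/S and DNA replication genes (−0.43) and neuroendocrine markers (−0.16) were lower. These 8 differences passed camera with a preset correlation, and 0 of them passed with an estimated correlation. The GADD and sterol differences were −0.02 and −0.11 on the deposited scale.

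Among 120 named genes, 5 had both DFO arrays on 1 side of both control arrays and both Dp44mT arrays on the other side. The differences, Dp44mT minus DFO, were −1.13 for RRM2 (limma unadjusted p = 0.000797), 0.71 for MVK (unadjusted p = 0.00886), 1.73 for SLC30A1 (unadjusted p = 0.0154), 0.45 for DHCR7 (unadjusted p = 0.0774) and −0.29 for HPRT1 (unadjusted p = 0.149), each with a limma adjusted p of 0.922. The placement depended on the scaling: it held for 0 of the 5 genes on the deposited scale and, with subtracted medians or linear scaling, for 1, SLC30A1. The SLC30A1 placement held on 1 of its 2 probe sets: the other was above control in DFO too (0.80 in set 1 and 0.04 in set 2), as well as in Dp44mT (2.59 and 3.56). Of the 3 other MVK probe sets, 1 was lower with both chelators (−0.45 in DFO and −0.05 in Dp44mT). Over all genes, 202 (1.20%) were placed in this way, against 2.22% for a chance order of the arrays. Among 8714 probe sets with no symbol or several, which the comparisons do not use, 21 passed in DFO (21 higher) and 78 in Dp44mT (45 higher, 33 lower).

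The 2 chelator arrays of set 2 lay apart from the other 4 on the first principal component. A chelator response larger in set 2 by 1 factor, as large as that of the spread of all genes, was argued against. The HIF list median was only 1.02 times as large in set 2 as in set 1 for DFO (bootstrap interval 0.926 to 1.26) and 1.13 times for Dp44mT (0.941 to 1.31), when the spread of all genes was 1.82 and 1.85 times as large. The intervals resampled the genes of the list and measure no spread between arrays. The spread of all genes also took in dim probe sets. Over 8324 genes with a second probe set, the deviation of the set 2 chelator arrays had an SD of 0.860, against 0.559 for the set 1 change. Over the 497 genes whose second probe set had a mean of 10 or over, the SDs were 0.270 and 0.496. A factor of 1.82 or 1.85 need not hold for bright genes, and a smaller common factor stays open. Other called lists went both ways: the ratio exceeded that of the spread for 1 of 13 lists in DFO (ribosome biogenesis) and 4 of 16 in Dp44mT (ribosome biogenesis, G1/S and DNA replication, metallothioneins and neuroendocrine markers) and was below 1 for 5 and 6, so a larger response of some gene groups stays open. RNA degradation stays open: the ACTB 3' to 5' ratio was above the range of the other 4 arrays on 1 of the 2 arrays, Dp44mT replicate 2 (1.41), which lay farthest out, and inside it on the other (1.30), while the GAPDH ratio was 0.967 (DFO) and 0.995 (Dp44mT) against 0.989 to 1.01 on the other arrays. The bounds of these 2 tests were revised after their first results had been seen. The answer on response size stayed, and degradation, first taken as argued against because of 1 array inside the range, became undecided. The deviation of these arrays correlated less between 2 probe sets of a gene than the set 1 chelator change did, by −0.356 (bootstrap interval −0.392 to −0.321 over 8324 genes), so signal of single probe sets rather than of transcripts may account for part of it. The correlations depended on brightness: 0.293 for the deviation and 0.649 for the set 1 change over all 8324 genes, and 0.699 and 0.907 for the 497 genes whose second probe set had a mean of 10 or over, where much of the deviation was thus common to both probe sets. What made that signal, and whether the cultures differed, stays open.

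Some markers of fibroblasts were higher on the set 2 chelator arrays, by a median of 3.50 for the brightest probe sets of COL1A2, COL3A1, DCN and POSTN, genes chosen for that rise. Over all 30 fibroblast marker probe sets the median was 0.14, and 7 rose by over 1. The brightest probe sets of LUM (−0.23 in DFO and −0.46 in Dp44mT) and THY1 (0.10 and 0.10) did not rise. Fibroblast RNA stays open. The other 7 probe sets of these genes past the filter changed by a median of 0.50 (quartiles −0.04 and 1.20), but 4 of them had means of 5.59 to 5.80, near the limit of 5.55, and decide little. A second POSTN probe set rose by 1.47 and 2.01, whereas 2 more DCN probe sets moved by −0.59 and 0.01 and by 0.57 and 0.84. Among those near the limit, a COL3A1 probe set rose by 1.69 and 1.71, with control at 5.97 in set 1 and 4.43 in set 2. The others near the limit moved by −0.10 and 0.41 (COL1A2), −0.36 and −0.09 (COL3A1) and 0.40 and 0.60 (DCN). COL1A1, an abundant fibroblast gene, moved by 0.12 (DFO) and 0.44 (Dp44mT) on its brightest probe set and by 0.81 and 1.30 on another. This test was revised after its result had been seen: it first took all 15 other probe sets (median 0.15, upper quartile 0.60) and then the 7 past the filter, both of which were read as evidence against fibroblast RNA, until the dim ones were discounted. The control array of set 2 was low, at a median of −1.62 from the lowest set 1 array. As the whole cause this was argued against for COL1A2, DCN and POSTN, where even the lower of the 2 set 2 chelator arrays lay above the highest set 1 array, by 1.17 to 1.35 after normalization and by 0.29 to 0.62 on the deposited scale. For COL3A1 it stays open, since that height was 0.61 after normalization, 0.20 with subtracted medians and −0.47 on the deposited scale. The bounds of this test, too, were revised after its result had been seen. PECAM1, 1 of 4 endothelial markers measured, had the same pattern, with changes of −0.57 (DFO) and −0.15 (Dp44mT) in set 1 and 2.47 and 2.83 in set 2, and the endothelium list stood at 0.96 and 0.93 in set 2. The PECAM1 control array was low in set 2 as well (9.32 in set 1 and 8.04 in set 2). KDR and TEK did not have the pattern. In both sets, KDR lay above control with DFO and below it with Dp44mT, and TEK lay above control with each chelator. A mixture of causes was not tested, and no biological explanation was tested.

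Metallothionein probe sets were higher on both Dp44mT arrays and on 1 of 2 DFO arrays, with medians of 1.43 and 3.46 for Dp44mT and 1.05 and −0.36 for DFO over the 9 probe sets whose names mark shared sequence. A single transcript behind these and MT3 was argued against, because MT3 differed from their median by −2.17 in set 2 of Dp44mT. For the 9 probe sets themselves, the Dp44mT changes averaged over both sets spanned 0.50. They ran from 0.77 to 1.67 in set 1 and from 2.85 to 3.72 in set 2. Separate genes and cross-hybridization of a single abundant transcript thus cannot be told apart with this array. Without such a name, an MT1M probe set that was dim in control followed the same pattern (1.32 and 6.04 for Dp44mT, 3.36 and −0.48 for DFO), and a dim MT1G probe set did not (−0.77 and 0.73, −0.25 and 0.22). Metal-responsive transcription in Dp44mT is a candidate explanation: SLC30A1, a zinc exporter of unrelated sequence, was above its control on both of its probe sets in both sets, by at least 0.45. SLC30A1 is a member of the same list, and the test was written after the pattern had been seen, so its rise is no independent support. In set 1 of DFO, where the metallothionein median was 1.05, its probe sets stood at −0.30 and 0.80. As a hypothesis, metal-responsive transcription remains untested outside these arrays, and the difference between the 2 DFO arrays stays open.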

How the results depend on the processing

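Linear scaling to a common median, array weights, leaving out both set 2 chelator arrays and the crossed pairing were chosen after the data were seen, and the other settings before. Every one of the 185 and 569 genes called kept its sign on the deposited scale, with subtracted medians and with linear scaling. The threshold left little room for a change of sign there. The smallest changes called were 2.36-fold (DFO) and 1.97-fold (Dp44mT), while the median log2 value of all genes on the deposited scale was −0.32 and −0.49. Leaving out arrays could not change a sign, because in all 185 and 569 genes both treated arrays lay on 1 side of both control arrays. The counts did not hold in the same way. For DFO, 185 became 26 on the deposited scale, 97 with the array medians subtracted, 112 with linear scaling, 278 probe sets with every probe set tested, 425 with trended and robust moderation, 61 with only the groups compared, 0 without both set 2 chelator arrays, 511 with the crossed pairing and 2 at an adjusted p under 0.01. For Dp44mT, 569 became 56 on the deposited scale, 247 with the medians subtracted, 314 with linear scaling, 1362 with trended and robust moderation, 907 with the set number as a block, 953 with a pseudocount of 64, 1010 with array weights, 844 without both set 2 chelator arrays (375 higher, 469 lower, 446 of them among the 569), 2758 with the crossed pairing and 46 at an adjusted p under 0.01. The genes shared by both chelators, 178, became 24, 83 and 100 with the 3 scalings in the order above, 2 at an adjusted p under 0.01 and 0 without both set 2 chelator arrays. Of the genes passing on the deposited scale, 19 of 26 (DFO) and 47 of 56 (Dp44mT) were among the main calls, and of those passing with subtracted medians, 84 of 97 and 206 of 247.

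Leaving out each array in turn gave 0 to 61 genes for DFO, 0 to 404 for Dp44mT, 0 to 0 shared genes, 5 to 8 lists called between the chelators and a correlation of fold changes of 0.632 to 0.922, against 0.755 without both set 2 chelator arrays. A group left with a single array is assumed there to vary like the others, and the fits have fewer arrays and residual degrees of freedom. Between Dp44mT and DFO, 0 genes passed in limma in every setting, with 96 to 2256 at an unadjusted p under 0.05. With an estimated correlation, 7 lists (DFO), 0 (Dp44mT) and 0 (between the chelators) passed, against 13, 16 and 8, and fry's directional test passed 0 between the chelators. Over all settings, 522 of 592 values of called lists kept camera's direction, which is relative to the other genes, and their side of the threshold, 70 lost the threshold and 0 turned. The list median itself took the other sign in 7 cases, 6 of them on the deposited scale. For named genes, 740 of 4115 values lost the threshold, 44 gained it and 2 called values turned: HK2, at −0.11 (DFO) and −0.38 (Dp44mT) with the mean of its probe sets. The other 3329 values were counted as the same. That count takes in every value called in neither setting, whatever its sign, and so all of Dp44mT against DFO, where 0 genes passed in every setting. Within the 3329, 20 values of 13 results called in neither setting took the other sign, RRM2 and CCND1 among them (−0.12 in DFO and −0.01 in Dp44mT on the deposited scale). On its brightest probe set TFRC passed only with trended and robust moderation (0.84 and 0.70), not with the crossed pairing (adjusted p = 0.0755 and 0.0556), and another TFRC probe set passed when every probe set was tested (adjusted p = 0.0433 and 0.0395).

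Same-numbered control and chelator arrays deviated in opposite directions from their group means (correlation −0.254 for DFO and −0.353 for Dp44mT across genes), whereas DFO and Dp44mT arrays of 1 number deviated together (0.843). As planned, the set number was left out of the main fit, and with the set number as a block 169 genes passed for DFO and 907 for Dp44mT. The changes given by set still subtract the control array of the same number, a pairing for which these correlations give no ground. Signal near background limits the values too: 10.1% to 20.3% of the probe sets of an array lay below the pseudocount of 16, most on Dp44mT replicate 2. Apart from the smaller numbers of arrays, probe sets and samples named here, the cause was not tested.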

Other observations

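The genes of this part were all chosen after their values were seen, and no explanation was tested for them. Some transcription factor genes outside the lists were lower in Dp44mT than in control. PROX1 fell by 5.05-fold in Dp44mT (log2 −2.34, SE 0.25, adjusted p = 0.0202), SOX2 by 3.30-fold (−1.72, SE 0.17, adjusted p = 0.0173) and SOX4 by 2.87-fold (−1.52, SE 0.24, adjusted p = 0.0429), with n = 2 arrays per group. BCL2, which encodes an inhibitor of apoptosis, fell by 4.72-fold (−2.24, SE 0.19, adjusted p = 0.0124). The medians of the other probe sets were −1.81 for PROX1 (2 of 3 lower), −0.70 for SOX2 (2 of 2), −1.19 for SOX4 (3 of 5) and −0.47 for BCL2 (2 of 3). In DFO these genes stood at −1.29, −0.42, −0.59 and −0.88, and none passed (adjusted p = 0.114, 0.372, 0.385 and 0.154). The differences, Dp44mT minus DFO, were −1.04, −1.30, −0.93 and −1.35, each with an adjusted p of 0.922.

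The genes next to NKX2-1 in chromosomal order were lower with it in Dp44mT. SFTA3, on 1 side, fell by 4.63-fold (log2 −2.21, SE 0.26, adjusted p = 0.0242) and NKX2-1-AS1, on the other, by 3.14-fold (−1.65, SE 0.23, adjusted p = 0.0362). The size of the NKX2-1-AS1 change depends on the pseudocount, because its Dp44mT mean (5.10) lay below the filter limit of 5.55. Farther out, PAX9 stood at −1.27 (adjusted p = 0.0704), MBIP at −0.86 (adjusted p = 0.0974), RALGAPA1 at −0.75 (adjusted p = 0.273) and SLC25A21 at −0.92 (adjusted p = 0.302). In DFO, SFTA3 stood at −1.13 and NKX2-1-AS1 at −1.13 as well (adjusted p = 0.167 and 0.138). Of 21 DUSP genes, the dual-specificity phosphatases, 5 rose and 0 fell in DFO and 6 rose and 0 fell in Dp44mT, among them DUSP10 (5.51-fold and 5.11-fold) and DUSP8 (3.38-fold and 4.54-fold). Of 17 Krüppel-like factor genes, 4 rose and 0 fell with each chelator, including KLF5 (5.01-fold and 5.57-fold) and KLF10 (4.68-fold and 4.75-fold). With any control array or any array of the chelator in question left out, 0 genes passed for either chelator in limma, these included (889 to 5443 at an unadjusted p under 0.05). CITED2, which encodes an inhibitor of HIF-dependent transcription, rose by 8.43-fold in DFO and 8.71-fold in Dp44mT. Its 2 other probe sets had medians of 1.25 and 1.09 on the log2 scale, but only 1 of the 2 was higher with each chelator.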
